A study of Mus musculus with 7 samples.

How the data were processed

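H3K27me3, the trimethylation of lysine 27 of histone H3 that Polycomb repressive complex 2 deposits over silent genes, was mapped by chromatin immunoprecipitation and sequencing in single livers of 7-week-old male CD-1 mice, an outbred stock. Per the labels' protocols, 3 mice received vehicle (DMSO in corn oil) and 4 received TCPOBOP at 3 mg/kg, and livers were taken 27 h later. TCPOBOP is a ligand that activates the mouse constitutive androstane receptor (CAR), a nuclear receptor that induces drug-metabolising enzymes in liver. Each sample came from a separate animal, so the spread between samples includes biological and technical variation.

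Per the submitters' processing notes, Bowtie2 2.3.2 and SICER 1.1 were used with the mouse genome build mm9. SICER joins windows that hold more reads than a random background into islands and was built for broad marks. The deposited values were one list of islands for each liver, with no pooling of livers, and a score for each island. The settings carried in the names of the lists were a window of 400 bp, a gap of 2400 bp and an E-value of 100. All 122262 islands were whole multiples of 400 bp and lay inside the mm9 chromosomes, whereas 837 would have run past the end of a chromosome of the later build GRCm38. No input control, filter or treatment of duplicate reads was given in the sources used here. The score is the authors' own value for an island and grows with both its length and the depth of the library. Its lowest, median and highest value and its value per window were compared between groups (exact permutation p = 0.0857, 0.171, 0.943 and 0.943). Because of depth, these comparisons were not read as effects of treatment. The score served to rank or filter islands within a list and to recover the read number. Divided by the number of windows, it served to set single islands beside the other islands of their own list and to describe whole lists. Islands were called in each liver against that library's own read number, so a change of the mark by the same factor everywhere would not appear in the lists. Absence of an island below means only that the list used here had none. Of the 23 regions among the top 10 by score of any list, 1 had no island at all in 3 lists, so the counts of shared and separated regions may hold absences that do not reflect the mark.

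The files gave no read numbers. In SICER 1.1 the score of a window is the negative natural log of a Poisson probability whose mean is set by the number of reads, so the read number was recovered as the whole number that gave the deposited scores of narrow islands to 12 significant digits, with an effective genome of 80% of mm9. The values recovered ran from 27939358 to 32536299 reads. Of 76 narrow islands tested, 61 were explained, some of which had served to choose among read numbers, and 0 of 280 tests with wrong read numbers succeeded. For vehicle replicate 1 only 2 of 4 islands were explained and both had served to choose its read number, so that value had no independent check. The method recovered 3 of 3 simulated libraries. In these, every window of an island held enough reads to be counted. Real islands can also hold windows that are not counted, so the simulation was an easier case. These read numbers rest on that model of the score and are those SICER counted, which need not equal the reads sequenced. SICER counts a window when it holds at least the number of reads reached by chance in at most 0.2 of windows; because reads are whole, the share reached by chance under the recovered depth differed between libraries, from 14.4% to 19.8% of windows.

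The number of islands, the length of genome under islands, the median island width and the share of island length on each of 21 chromosomes were compared between groups with two-sided exact permutation tests over all 35 splits of the 7 samples into 3 and 4, for which the smallest p is 0.0286. Intervals of differences are 95% intervals found by inverting the same test. Overlap of 2 lists was measured with the Jaccard index, the base pairs shared divided by those in either list, and tested one-sided for higher values within groups than between them. Islands of all 7 lists were merged where they overlapped or touched, which gave 17394 regions. The fraction of each region under islands was compared with limma 3.58.1 (trend and robust variance; R 4.3.3) in the 13988 regions that had an island in at least 2 livers and did not have the same fraction in all of them, with Benjamini-Hochberg adjustment and a threshold of 0.05. Regions with an island in all livers of 1 group and in none of the other were counted as separated, and set against the same count in the other splits. Other computations used Python 3.11.15, NumPy 2.4.6 and SciPy 1.17.1.

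The limma comparison was tested on simulated data in which 200 of the 13988 regions lost cover in 1 group. These data were the real covers with the real groups, and the other regions were left as they were. It recovered 0% of them even when all cover was lost, so its count of calls cannot show that cover was unchanged. Without trend and robust variance limma recovered 71.5% of complete losses, 41.0% when 25% of the cover was kept and 0% when 50% was kept. It also called 37, 32 and 13 of the regions left as they were. These calls are not known to be false, since real differences between the groups remained in the data. With no region altered it called 13. For that reason a further statistic was added after the data were examined: regions whose groups did not overlap and whose mean cover differed by at least 25% of the region. It found 100%, 95.0% and 73.5% of the same simulated changes. With 200 changed regions its total was 455 to 509, which includes regions already apart in the unaltered data (310 with no region altered). That total stayed below the highest of another split of the livers, 740 to 742. With 0%, 25% and 50% of the cover kept, 9, 9 and 13 splits of the livers, the real one included, gave as many. In the unaltered data, splits with vehicle replicate 2 and TCPOBOP replicate 2 on one side gave 396 to 746. The other splits with them apart, like the real one, gave 237 to 306, below the simulated totals. A rank among all splits therefore cannot decide whether 200 such changes would have stood out.

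The rule for naming regions was fixed before the data were examined: 10 in each direction by the difference in base pairs covered, first those past the threshold and then those separated by group, and the 5 regions shared by all 7 livers with the highest summed cover. The regions with the highest scores, the X and Y regions and the block of chromosome 2 were chosen after their values were seen. The tests, their designs and the alternatives were also fixed before the data were examined, except those named in the closing section as added. Fits of genes and of 15 gene lists had been planned only for the case that gene positions in mm9 were at hand. The gene table used here is of the assembly GRCm38.p6, whose coordinates cannot be set against mm9, so genes were not analysed here. That table served only to count protein-coding genes on each chromosome. Alternatives tried were the higher-scoring part of each list, lists of equal total length, only islands of at least 4 kb, other definitions of overlap and presence, bins of 10 kb, covariates, other limma settings, a replicate block and leaving out each liver in turn.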

Results

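H3K27me3 islands were mapped in 7 livers of adult male mice, 3 from mice given vehicle and 4 from mice given TCPOBOP, 27 h after a dose of 3 mg/kg. The comparison asked what the CAR ligand did to the repressive mark in liver. The read numbers recovered from the scores were 29533929, 27939358 and 32536299 for vehicle replicates 1 to 3 and 31419033, 32388020, 32292090 and 32154814 for TCPOBOP replicates 1 to 4. All coordinates are in mm9.

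H3K27me3 islands covered a similar part of the genome in both groups. They spanned 569 ± 27.5 Mb (SD, n = 3), or 21.4 ± 1.04% of the genome, in vehicle livers and 579 ± 29.2 Mb (SD, n = 4), or 21.8 ± 1.1%, in TCPOBOP livers. The difference of 10.2 Mb was smaller than the spread between livers (95% interval -87.6 to 69.5 Mb, exact permutation p = 0.514). Vehicle replicate 2 and TCPOBOP replicate 2 had the least genome under islands of their groups, 537 Mb in each, and the other livers had between 583 and 605 Mb. Without vehicle replicate 2 the difference turned to -5.65 Mb.

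TCPOBOP livers had 18486 ± 1662 islands (SD, n = 4) and vehicle livers 16107 ± 1850 (SD, n = 3). The difference of 2379 islands did not pass the test (95% interval -2298 to 7196, exact permutation p = 0.143), and without vehicle replicate 1 it was 1409. Counts ran from 14167 in vehicle replicate 1 to 20550 in TCPOBOP replicate 1. The median island width was 26.4 ± 4.18 kb (SD, n = 3) with vehicle and 22.7 ± 1.28 kb (SD, n = 4) with TCPOBOP, a difference of -3.70 kb that did not pass the test (exact permutation p = 0.0571). Vehicle replicate 1, with a median width of 31.2 kb, set most of that difference: without it the difference was -1.30 kb. The share of windows counted by chance under the recovered depth was 17.6 ± 1.98% (SD, n = 3) in vehicle and 15.7 ± 0.857% (SD, n = 4) in TCPOBOP libraries (exact permutation p = 0.0571), and was highest in vehicle replicate 1, at 19.8%, a library whose recovered read number had no independent check.

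**Figure D1:**
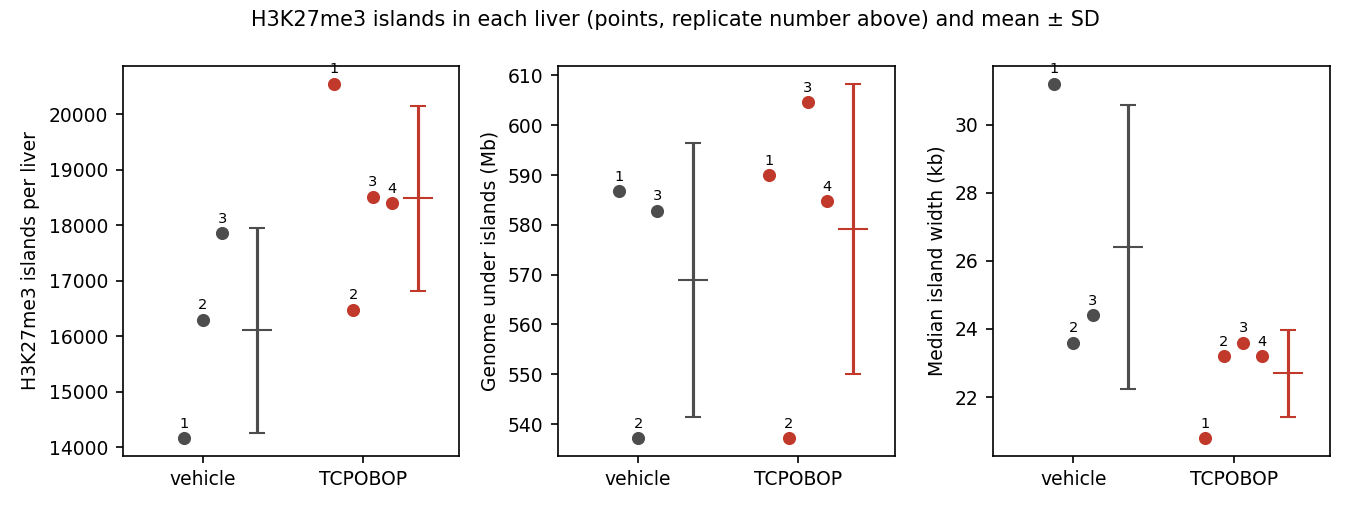
Number of islands, genome under islands (Mb) and median island width (kb) in each of 3 vehicle and 4 TCPOBOP livers; points are livers, numbers above them are replicate numbers, and bars are means ± SD. The axes do not start at 0. Vehicle replicate 1 had the fewest islands (14167) and the greatest median width (31.2 kb).

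Of the regions with an island in all 7 livers, the 5 with the highest summed cover lay on chromosomes 12, 16, 8, 9 and 7. The widest, on chromosome 12 from 107577201 to 109103600, was 1526 kb long and 78.8 ± 4.87% of it was under islands with vehicle (SD, n = 3) and 82.8 ± 4.06% with TCPOBOP (SD, n = 4). On chromosome 16 from 92614801 to 93579200 the cover was 89.4 ± 4.06% and 89.2 ± 1.68%. The region on chromosome 8 from 11937201 to 12627600 was 99.2 ± 0.729% and 99.0 ± 0.268% covered. The region on chromosome 9 from 49186401 to 49859200 was 97.6 ± 1.01% and 97.0 ± 0.484% covered, and that on chromosome 7 from 139191601 to 139852800 was 95.9 ± 2.69% and 95.8 ± 2.53% covered.

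The top 10 islands by score of the 7 lists fell in 23 regions, of which 4 were in the top 10 of all 7 lists and 10 in that of 1 list. The chromosome 8 region held the island ranked 1 by score in 6 of 7 lists. A region on chromosome 15 from 102550801 to 102923600 ranked 1 in the list of vehicle replicate 1. It was among the top 10 of all 7 lists, as were regions on chromosome 6 from 51972401 to 52298400 and on chromosome 19 from 44640001 to 44936400. Cover in these 3 regions was 97.1 ± 2.40%, 93.3 ± 1.42% and 97.1 ± 1.42% with vehicle (SD, n = 3) and 96.6 ± 1.25%, 95.3 ± 2.05% and 95.0 ± 1.89% with TCPOBOP (SD, n = 4). A region on chromosome 2 from 74432401 to 74663200 was in the top 10 of 6 lists.

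Islands of the 7 livers merged into 17394 regions that spanned 916 Mb. Of these, 6624 regions (38.1%) had an island in all 7 livers and 3406 had an island in only 1 liver. Regions found in all livers were longer, with a median of 68.0 kb, than those found in 1, with a median of 18.0 kb. Part of this follows from the merging, since a region joins the islands of every liver that has it. The genome under islands in all 7 livers came to 266 Mb, 29.0% of that under islands in any of them.

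Livers given the same treatment did not share more of their islands than livers given different treatments. The mean Jaccard index was 0.612 over 9 pairs within groups and 0.615 over 12 pairs between groups, a difference of -0.00362 (one-sided exact permutation p = 0.571), and without vehicle replicate 2 it turned to 0.00251. The index ranged from 0.590 to 0.649 and was highest for vehicle replicate 2 with TCPOBOP replicate 2. TCPOBOP replicates 3 and 4 followed, at 0.641.

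**Figure D2:**
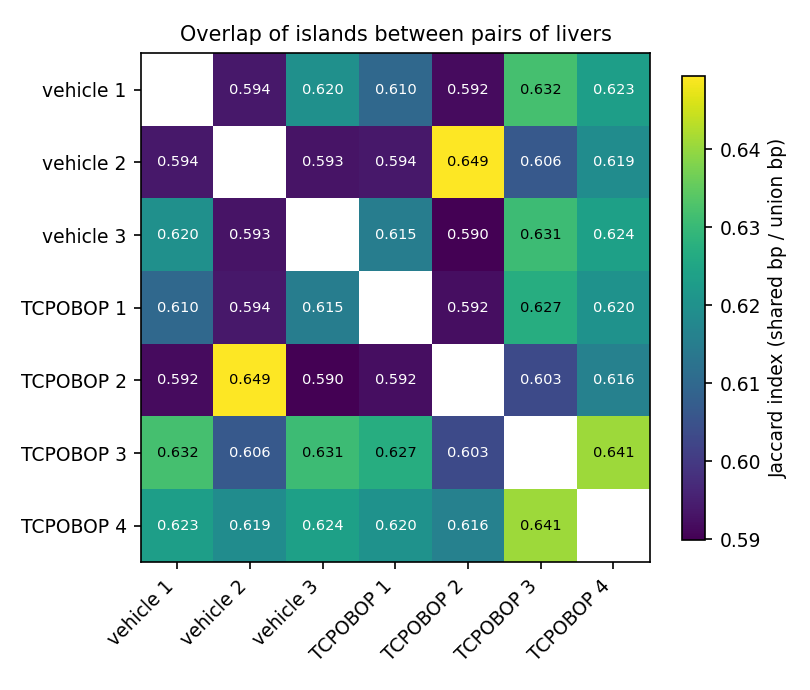
Jaccard index (base pairs shared over base pairs in either list) for the 21 pairs of the 7 livers, in color and in numbers. The highest value, 0.649, joins vehicle replicate 2 and TCPOBOP replicate 2, a pair of different treatment.

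No shift of the mark from one chromosome to another was detected. Chromosome 11 had the highest cover, 32.3 ± 0.188% of its length with vehicle (SD, n = 3) and 33.1 ± 0.803% with TCPOBOP (SD, n = 4), followed by chromosome 9 with 30.9 ± 0.839% and 31.5 ± 1.43%. Chromosomes 10 and 3 had the lowest cover of the autosomes, 16.9 ± 1.45% and 17.0 ± 1.76% with vehicle and 17.4 ± 1.47% and 17.8 ± 1.89% with TCPOBOP. The share of all island length on a chromosome passed the test for 0 of 21 chromosomes (exact permutation tests, adjusted p = 0.943 for each, 0 at an unadjusted p under 0.05). With a smallest p of 0.0286 before adjustment over 21 chromosomes, a shift of 1 or a few chromosomes could not have passed.

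The X chromosome was almost free of islands. Islands covered 0.164 ± 0.109% of it with vehicle (SD, n = 3) and 0.157 ± 0.0541% with TCPOBOP (SD, n = 4). The length of X under islands was 273 ± 182 kb and 262 ± 90.2 kb (exact permutation p = 0.971). Vehicle replicate 2 had 478 kb, and without it the vehicle mean was 169.8 kb and the difference turned to 92.2 kb more with TCPOBOP (exact permutation p = 0.333); without TCPOBOP replicate 3 it turned to 22.1 kb. The X islands merged into 45 regions, of which 5 were found in all 7 livers and 18 in 1 liver, 15 of these in vehicle replicate 2. On Y there were 8 regions, 3 of them in all 7 livers. The Y region from 1787601 to 1795200 had scores per window of 182 to 258 in the 7 lists, against medians over all islands of 2.56 to 3.05.

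**Figure D3:**
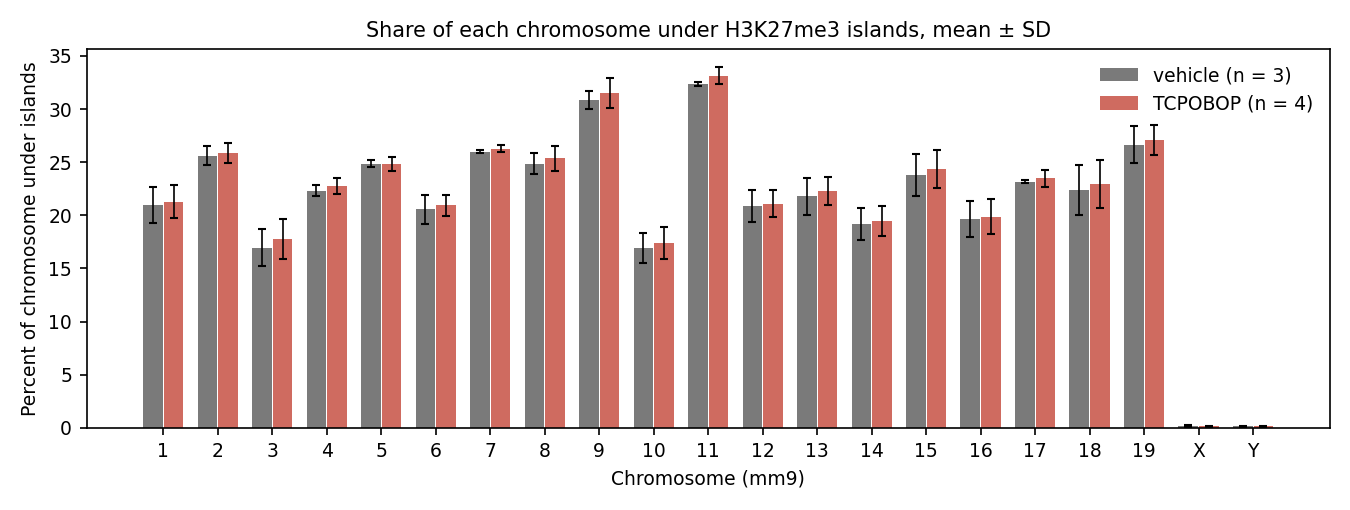
Percent of each mm9 chromosome under islands with vehicle (gray, n = 3) and TCPOBOP (red, n = 4); bars are means and error bars SD. Chromosome 11 had the highest cover (33.1% with TCPOBOP), and X and Y had less than 1%.

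Regions that differed most between the groups were of moderate width and none passed the test. Of 13988 regions tested with limma, 0 had an adjusted p under 0.05 and 542 (3.87%) had an unadjusted p under 0.05; the lowest adjusted p was 0.731. Without trend and robust variance limma called 13 regions, 10 with more and 3 with less cover after TCPOBOP. With that setting 26 of the 35 splits of the livers, the real one included, gave 13 or more calls. The median of the other splits was 17.5, so these calls were not read as effects of treatment. The median standard error of the difference was 24.0% of a region's length. In simulated data the test recovered 0% of complete losses, so changes of single regions were not detectable with it.

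Of the merged regions, 45 had an island in all 4 TCPOBOP livers and in 0 of 3 vehicle livers, and 15 had an island in all 3 vehicle livers and in 0 of 4 TCPOBOP livers. With lists of equal total length the counts were 34 and 22, and 10 of the 35 splits of the livers gave 45 or more regions with islands only in the 4. The median length was 29.2 kb for the former and 35.2 kb for the latter. Among the regions with islands only after TCPOBOP, the longest cover was on chromosome 3 from 54955601 to 55001600, where islands spanned 39.1 ± 3.79 kb of 46.0 kb (SD, n = 4). Its covered fraction differed by 0.85 (SE 0.262, limma adjusted p = 0.768). On chromosome 7 from 57582801 to 57620400 the islands spanned 33.8 ± 4.96 kb (difference in fraction 0.899, SE 0.249, limma adjusted p = 0.731). The region on chromosome 6 from 101820001 to 101882000 had 33.5 ± 14.99 kb under islands, that on chromosome 2 from 170915201 to 170965600 had 28.8 ± 12.5 kb, and that on chromosome 10 from 51778801 to 51828400 had 27.6 ± 6.51 kb. The other 5 by the same rule lay on chromosome 7 from 76149601 to 76209600, chromosome 17 from 59249201 to 59297200, chromosome 9 from 24084801 to 24124800, chromosome 14 from 12026401 to 12064000 and chromosome 6 from 109152801 to 109184800. Their mean cover with TCPOBOP was between 26.4 and 27.5 kb.

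Among the regions with islands only in vehicle livers, the longest cover was on chromosome 6 from 139328801 to 139388000, with 38.8 ± 14.6 kb of 59.2 kb under islands (SD, n = 3; difference in fraction -0.66, SE 0.315, limma adjusted p = 1). The region on chromosome 5 from 15798401 to 15865200 had 38.0 ± 11.5 kb, that on chromosome 13 from 115644401 to 115691600 had 32.4 ± 9.46 kb, that on chromosome 10 from 7993601 to 8030800 had 29.6 ± 6.58 kb and that on chromosome 13 from 117675201 to 117719200 had 29.2 ± 7.21 kb. The other 5 lay on chromosome 10 from 109454801 to 109490000, chromosome 13 from 11482001 to 11514000, chromosome 11 from 92258801 to 92286000, chromosome 5 from 17811201 to 17849600 and chromosome 15 from 76645201 to 76681200. Their mean cover with vehicle was between 23.9 and 28.4 kb. The lowest adjusted p of all 60 separated regions was 0.731 (limma).

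In regions found only after TCPOBOP the best island of a liver had a median score percentile of 24.3 within its own list and a highest of 75.0, and in regions found only with vehicle 23.5 and 52.9. Of the 35 ways to split the livers into 4 and 3, 16, the real one included, gave 60 or more separated regions, the median of the others was 54.5 and the highest was 182. A statistic added after the data were examined, in which the groups had only to be non-overlapping and to differ by at least 25% of the region, counted 310 regions, of which 167 had more and 143 less cover with TCPOBOP. For values without ties, chance alone separates groups of 3 and 4 in 5.71% of regions.

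**Figure D4:**
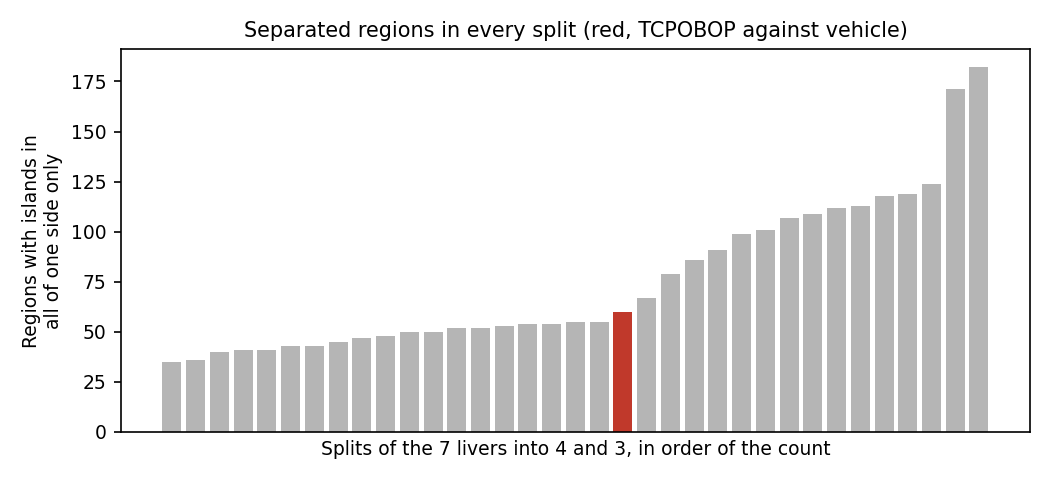
Number of merged regions with islands in all livers of one side and in none of the other, for each of the 35 splits of the 7 livers into 4 and 3, in increasing order. The split by treatment (red) had 60 regions and the highest of the other splits 182.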

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

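The tests of read number, of the read minimum, of gene density, of the chromosome 2 block and of other splits of the livers were written after their results had been seen. Those of a width difference with the trend taken out and of X with fewer reads were written before.

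Among 29 measures of the 4 TCPOBOP livers, 4 had a liver far from the other 3; chance puts about 1 in 20 there. TCPOBOP replicate 1 had a median island width of 20.8 kb against 23.2, 23.2 and 23.6 kb in the others. TCPOBOP replicate 2 had 8.30% of its island length on chromosome 2 against 8.04 to 8.07%, 6.86% on chromosome 5 against 6.42 to 6.48%, and 3.31% on chromosome 18 against 3.68 to 3.69%. Vehicle replicate 2 had similar shares, 8.31%, 7.05% and 3.32%, and the other vehicle livers had 8.11 to 8.15%, 6.42 to 6.55% and 3.68 to 3.69%.

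Vehicle replicate 1 had the fewest and widest islands and TCPOBOP replicate 1 the most and narrowest. A candidate explanation is the whole-number read minimum of a counted window: the share of windows that reach it by chance rose with median width over the 7 libraries (Spearman rho 0.837, exact permutation p = 0.0270, adjusted 0.0768; Pearson r 0.991, exact permutation p = 0.00238, adjusted 0.00714, over 9 relations computed; r 0.778 without the 2 libraries farthest from the median share). With the number of islands the share had r -0.891 (exact permutation p = 0.0103, adjusted 0.0232), but -0.315 without the 2 farthest, and rho -0.821 (adjusted 0.0768). With the lowest island score, highest in vehicle replicate 1 at 100.7, it had r 0.997 (adjusted 0.00357), and 0.940 without the 2 farthest. Under the model of the score both values depend on the read number and the settings of SICER. This relation is therefore no separate support for the explanation of width. The read number of vehicle replicate 1 has no independent check. Without that library the relation with width had rho 0.736 (exact permutation p = 0.122) and r 0.974 (exact permutation p = 0.0167), so it stays open. The number of reads itself also stays open: vehicle replicate 1 lay between vehicle replicate 2 and TCPOBOP replicate 1 in reads and was 7.60 kb wider than the wider of these, but this rests on the same unchecked number, and r of reads with width was -0.377 over 7 libraries (exact permutation p = 0.409; rho -0.0364, exact permutation p = 0.956; adjusted 0.460 and 0.963) and 0.973 without the 2 farthest, while without vehicle replicate 1 alone r was 0.0289 (exact permutation p = 0.894) and rho 0.412 (exact permutation p = 0.433). After a linear trend on the share was taken out, the group difference in median width was -0.0201 kb (exact permutation p = 0.943), but groups and share differ together, so an effect of treatment on width stays open.

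X was almost free of islands in all 7 livers, and the tables argue against a low number of genes as the cause. The autosomes with at most 1 gene per Mb more than X had a mean cover over the 7 libraries of 17.4% or more. The lowest cover in a single library was 14.9%, for chromosome 3 in vehicle replicate 2. Males carry a single X, so its windows may hold fewer reads under a threshold set for the whole genome. Islands on autosomes whose mean window would keep the read minimum with the reads of 1 copy covered 0.285% of the autosomes (mean of 7 libraries). That was 1.78 times the 0.160% of X that was covered, a ratio under the bound of 5 set before it was computed. The mean rests on the libraries numbered 2: without vehicle replicate 2 it was 0.168% and without both 0.0888%, 1.21 and 0.733 times the X cover of the rest, and single libraries ran from 0.326 to 3.45 times. Counting an autosomal island required a mean score per window of 8.78 to 10.3, against medians over all islands of 2.56 to 3.05, so few could count. An island is kept on its summed score, so wide but less dense islands might also be kept with fewer reads. The ratio therefore cannot decide whether a single copy of X is the source. A true lack of the mark on X was not tested, and both stay open.

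A block on chromosome 2 from 77692801 to 77866000 held 5 islands with scores per window of 26.3 to 102 in vehicle replicate 2, 11.2 to 23.1 in vehicle replicate 1 and 6.46 to 13.4 in TCPOBOP replicate 1, whose medians over all islands were 3.02, 2.56 and 2.65; scores depend on depth and were read only within a list. The tables argue against treatment, since 3 of the 4 TCPOBOP livers lacked this density, with islands of at most 3.63 or none there, and 2 of the 3 vehicle livers had it. Extra copies of the segment in some animals of this outbred stock may be the source: 87.5% of the 8 inner edges lay within 1 window in the 3 libraries, against 18.0% of 200 edges of 100 islands elsewhere that were also dense in these 3 libraries. The edges of 1 block are not independent, and sharp edges could also belong to a domain that differs between animals for another reason, so this stays open.

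Chance could not be excluded for the regions that separated the groups. For separated regions 16 of the 35 splits gave 60 or more. The highest of the others was 182, for vehicle replicate 3 with TCPOBOP replicates 1, 3 and 4 against the rest. Those 4 lists had the most islands, 17852 to 20550 against 14167 to 16481 in the rest. Of the 182 regions, 167 had islands only in those 4 livers and 15 only in the rest. The highest count thus went with the number of islands in a list, but this split also had both libraries numbered 2 on one side. Splits with both on one side gave 53 to 182 separated regions. Splits with them apart gave 35 to 67, and the real one had 60. The next highest count, 171, put vehicle replicate 1 and TCPOBOP replicate 1, with the fewest and the most islands, on the same side. The number of islands alone therefore does not account for the counts, and their sources were not tested. Of groups that did not overlap and differed by at least 25% of the region, the real count was 310, again in 16 of the 35 splits, and the highest of the others was 746. That rank went with the libraries numbered 2: splits with both on one side gave 396 to 746. The other splits with them apart gave 237 to 306, just below the real 310. At 50% of the region they gave 93 to 127, and the real split gave 130. These margins are small and the comparison was made after the counts were seen, so it decides nothing. With limma the real count was 0, so all 35 of the 35 splits had to give as many (highest of the others 0), which tests nothing.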

How the results depend on the processing

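The alternatives named here as added were chosen after seeing the data. No alternative brought the number of islands (10 tried, differences 1190 to 3252), the genome covered (10), the median width (10, differences -5.27 to -1.30 kb), the overlap (12) or a chromosome's share (7, all added) past the test's threshold. The smallest p allowed is 0.0667 or 0.1000 when a liver is left out, so those tests could not have passed. The difference in genome covered reversed to -5.65 Mb without vehicle replicate 2 and ran to 24.2 Mb without TCPOBOP replicate 2; that in overlap reversed to 0.00251 without vehicle replicate 2 and was otherwise negative, down to -0.00836. The difference in the length of X, leaving livers out as added alternatives, ran from -82.0 to 92.2 kb and reversed without vehicle replicate 2 (92.2) and TCPOBOP replicate 3 (22.1), the vehicle liver with the longest and the TCPOBOP liver with the shortest X cover, 478 and 164 kb. For genome covered and overlap the cause was not tested.

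Separated regions numbered 91 (57 only with TCPOBOP, 34 only with vehicle) when at least 50% of a region had to be covered, 27 (25 and 2) in the higher-scoring part of each list, and 117 to 264 when each liver was left out in turn, where fewer livers have to agree. Added alternatives gave 460 without both libraries numbered 2, a count reached by 2 of 10 splits, too few for a share under 0.05, with 460 also the highest of the others. Added alternatives without overlap of the groups gave 310 at 25% and 130 at 50% of the region. Limma called 13 regions without trend and robust variance, against 4 to 81 in the other splits, 1 with no minimum number of livers, and 0 to 6 when each liver was left out (4 without vehicle replicate 1, 6 without vehicle replicate 3). The share of windows counted by chance as a covariate, added, gave 2. The remaining limma alternatives gave 0. Over all 18 limma alternatives the lowest adjusted p ranged from 0.00486 to 0.994.

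With the replicate block limma called 0 regions, as without it. Deviations of livers with the same number correlated at 0.0228, 0.218 and 0.0483, so the numbers were not taken to pair the livers. Alternatives for genes and gene lists were not run, since no gene positions in mm9 were used here. Depth limits the lists themselves: islands below the threshold of a library were not seen.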

Other observations

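The test of gene density was chosen after the result was seen. Cover followed the gene content of the autosomes. Over 19 autosomes the mean percent covered rose with protein-coding genes per Mb (gene counts of GRCm38.p6 over mm9 lengths; Pearson r 0.726, permutation p = 0.00045; Spearman rho 0.723, permutation p = 0.00079; r 0.628 without the 2 chromosomes farthest from the median density). Chromosomes are not replicates. In single livers r ran from 0.678 in vehicle replicate 1 to 0.783 in vehicle replicate 2. This is consistent with the mark lying mainly in gene-rich parts of the genome, but GC content and the share of sequence that reads can be placed in were not tested.

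Vehicle replicate 2 and TCPOBOP replicate 2 had the highest overlap although their treatments differed. Their Jaccard index was the highest of 21 pairs, 0.649 in the lists as deposited and 0.649 in lists of equal total length, where the next was 0.636. Their mean scores per window over the whole list were 4.15 and 4.04, against 2.93 to 3.41 in the other 5 livers, with the limit that scores depend on depth. Over the 7 libraries that score ran with the length of X under islands (Pearson r 0.951, exact permutation p = 0.00238, adjusted 0.00714; Spearman rho 0.857, exact permutation p = 0.0238, adjusted 0.0768; r 0.728 without the 2 libraries farthest from the median score). Its relation with the genome covered rested on the 2 farthest libraries (r -0.900, exact permutation p = 0.0256, adjusted 0.0461; rho -0.679, exact permutation p = 0.110, adjusted 0.197; r 0.108 without them). These are 2 of the 9 relations computed, and the libraries numbered 2 stand apart from the rest in the score.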
